A study of Canis lupus familiaris with 12 samples.

How the data were processed

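Beagle dogs had been assigned to a sham arm or to an arm with rapid atrial pacing for 2 weeks, per the labels. Pacing of this kind drives the atria electrically at a high rate and is used to induce atrial fibrillation. Messenger RNA from hippocampus and microRNA from exosomes of left atrial epicardial fat (EAT) were sequenced, with 3 samples per arm in each tissue and 12 samples in all. The hippocampal libraries were made with a stranded mRNA kit, per the labels' protocols. The kit used for the exosome libraries is not given in the sources used here.

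Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.3a and featureCounts were used; their order, the annotation release, the strand setting and the handling of molecular identifiers are not stated. The deposited hippocampal values are RPKM, reads scaled to the summed exon length of a gene and to the reads assigned to genes in the library, for 31158 gene models. The sequence names in that table are those of the dog assembly CanFam3.1, and all coordinates below are on that assembly as the deposited table gives them. RPKM multiplied by the length column returned whole reads for every value in each of the 6 hippocampal libraries, so the read totals are known. The deposited exosome file is named TPM but holds RPM, reads scaled to the listed reads of the library, with no length term, since every value is a whole multiple of 1 step per library and each library sums to the same total. It lists 321 entries, 178 with a dog miRNA name and 143 numbered entries written novel_ and a number. The miRNA reference and the caller of the numbered entries are not given in the sources used here.

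Values were analysed in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Hippocampal genes with a mean RPKM of at least 0.5 over the 6 libraries were tested with limma-trend on log2(RPKM + 1). Exosome entries with a mean RPM of at least 10 were tested with limma-trend on log2(RPM + 1). Differences are pacing minus sham, and p-values were adjusted by the Benjamini-Hochberg method at 0.05 over all features tested in a tissue. They measure the spread between samples; the labels do not state that each sample came from a separate dog. Lists of genes and miRNAs were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 tested genes or 4 tested miRNAs. Camera with an estimated correlation and fry were run beside it. Single members of a list were also adjusted over the list alone. Of 37 gene lists, 35 were tested, and of 15 miRNA lists, 14 were tested. The erythrocyte and sex-linked gene lists and the epithelial miR-200 list had too few tested members.

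Group assignments, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with a symbol of largest rise and of largest fall among those past the threshold, filled up by the smallest p in each direction where fewer passed. It had gene models without a symbol counted and not named, and the text departs from it by naming the 4 that passed, chosen after their values were seen. BDNF, NFE2L2, KEAP1 and APP were named in advance. For the exosomes the rule took miRNAs in the same way, 8 in each direction, and the 8 most abundant miRNAs. It was applied to miRNAs with a name, and the 3 passing numbered entries are given beside them. From each list the rule took up to 3 members with the smallest p and those passing over all genes. Members past the threshold adjusted over the list alone are given as well. Genes chosen after their values were seen are called so where they are named. Some genes that the rule took are not reported here. Gene symbols are those of the deposited table, of which 25961 also occur in a RefSeq gene table of assembly UU_Cfam_GSD_1.0. That table was used for gene type and gene order only.

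Ratios of read shares carry an exact 95% interval, and a group with no reads was set at a floor of 3 reads over the arm. These intervals and floors cover counting error only. Alternatives changed the pseudocount, the low-value filter, the scaling between libraries (median of ratios or quantile), the sample weights, the variance trend, the threshold and the test (edgeR's quasi-likelihood test on recovered reads), added the replicate number as a block, and left out each library in turn. Added after the data were seen were exosome values scaled to the reads of named miRNAs alone and quantile scaling for the list tests. DESeq2 and the alternatives for deposited count tables were not run, because no table holds counts. Tests of miRNA seed families and of annotation terms were not run, because no 3' UTR sequence or annotation terms were used here.

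The tests were tried on simulated reads drawn from the real means and library totals. Hippocampal reads had a single dispersion of 0.0475 for all genes and both arms. The shares found in hippocampus therefore need not hold for genes or libraries that vary more. Of 50 genes changed in hippocampus at each fold, limma found 14% at 1.5-fold, 52% at 2-fold, 96% at 4-fold and 100% at 8-fold, among 16057 tested genes and with 9 of 140 calls false. With the dispersion of the exosome reads, 0.893, it found 0 of 5 entries at each of these folds among 301 tested entries. With a dispersion of 0.02 it found 0 of 5 at 1.5-fold, 0 of 5 at 2-fold, 3 of 5 at 4-fold and 3 of 5 at 8-fold, among 309 entries. In a simulated hippocampus with 16068 tested genes, 1 list was moved by 1.5-fold. Camera called that list and 0 of the other lists. Because the simulated genes varied independently, this trial could not test how often camera calls a list whose members vary together.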

Results

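Hippocampal mRNA and epicardial-fat exosome miRNA were profiled in beagles after a sham procedure or 2 weeks of rapid atrial pacing, with 3 samples per arm in each tissue. The design addresses how atrial fibrillation relates to cognitive impairment, through vesicles shed by the fat that lies on the heart. Hippocampal libraries held 39777115 ± 4322410 assigned reads in pacing and 46099179 ± 8301720 in sham (SD, n = 3 each; 35003483 to 51789497 per library). Reads were found on 25823 ± 205 gene models in pacing and 26549 ± 703 in sham. Exosome libraries were shallow, with 13662 ± 2141 listed reads in pacing and 17547 ± 6673 in sham, between 12159 and 25171 per library. Named miRNAs took 50.5 ± 10.1% of these reads in pacing and 54.8 ± 20.7% in sham, from 36.5% in sham replicate 1 to 77.3% in sham replicate 2.

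Hippocampal libraries correlated across genes at Pearson r of 0.993 to 0.994 within pacing, 0.968 to 0.981 within sham and 0.972 to 0.989 between arms; genes are not independent replicates. Sham replicate 2 stood apart, at 39.6 on a first principal component that held 45.3% of the variance. Sham replicate 3 was at 8.61, and the other 4 libraries lay between -13.5 and -9.62. On the second component, with 25.5% of the variance, sham replicate 3 stood apart at -29.1, and all other libraries lay between -6.21 and 13.6. No library pair within an arm agreed within sampling noise, with chi-square per degree of freedom from 9.65 to 150 in hippocampus and from 55.8 to 113 in exosomes.

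The comparison of pacing with sham hippocampus asked which transcripts differed in the brain of paced dogs. The clearest differences lay in 4 gene models without a symbol, and no gene with a symbol passed. LOC102155886, a protein-coding model on chromosome 21 from 40629290 to 40633680 beside serum amyloid A genes, fell from 6.49 ± 0.217 RPKM in sham to 0.274 ± 0.0985 in pacing (SD, n = 3 each; log2 change -2.56, adjusted p = 4.05e-04). LOC106558560, on an unplaced sequence from 674 to 1072, rose from 0.0457 ± 0.0791 to 19.3 ± 5.14 RPKM (log2 change 4.25, adjusted p = 5.51e-04). LOC102151856, on chromosome 15 from 49438852 to 49439253, rose from 1.43 ± 0.231 to 18 ± 3.06 RPKM (log2 change 2.96, adjusted p = 5.89e-04). LOC102152881, a long non-coding RNA on chromosome 37 from 129084 to 139132, rose from 1.77 ± 0.162 to 11.4 ± 2.15 RPKM (log2 change 2.15, adjusted p = 0.00366).

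The read numbers behind the passing models were 23 in pacing against 640 in sham for LOC102155886, a 24.0-fold difference in read share (95% interval 15.9 to 38.2). They were 936 against 2 for LOC106558560 (542-fold, 150 to 4485), 876 against 80 for LOC102151856 (12.7-fold, 10.1 to 16.2) and 879 against 161 for LOC102152881 (6.33-fold, 5.34 to 7.53). Other genes near LOC102155886 on chromosome 21 were also lower in pacing without passing; all but SAA1, which the rule took, were chosen after their values were seen. SAA1, an acute-phase protein gene, stood at 0.748 ± 0.0836 against 2.32 ± 0.42 RPKM (log2 difference -0.92, adjusted p = 0.151), LOC476879 at 1.45 ± 0.325 against 3.55 ± 0.991 (-0.88, adjusted p = 0.301) and LOC111089962 at 1.24 ± 0.0977 against 1.96 ± 0.0862 (-0.40, adjusted p = 0.334). SAAL1, on the other side, did not separate the arms (log2 difference -0.07). Reads shared between near-identical serum amyloid A copies cannot be resolved from this table.

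Of 16090 genes tested with limma, 12741 of them with a symbol, 3 rose and 1 fell; 0 genes with a symbol passed, while 953 of them had an unadjusted p under 0.05. edgeR on recovered reads called 6 genes (4 higher, 2 lower). At an unadjusted p under 0.05 there were 459 higher and 1014 lower genes, and the median gene differed by a log2 value of -0.04. All pacing libraries lay on 1 side of all sham libraries for 2605 genes, 16.2% of those tested, where chance gives 10%, and 2220 were in the highest of the other splits of the 6 libraries. The count of passing genes was 95 without sham replicate 1, 9 without sham replicate 2, 7 with no filter and 23 with library weights. With median-of-ratios scaling 3 genes rose and 2 fell.

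The named genes next in line were higher or lower in every pacing library than in every sham library, and none of them passed. TNFRSF1B, a receptor for tumour necrosis factor, stood at 17.8 ± 2.21 RPKM in pacing and 8.43 ± 1.37 in sham (adjusted p = 0.151). SELPLG, the leukocyte ligand of P-selectin, stood at 10.9 ± 0.206 against 6.59 ± 0.347 (adjusted p = 0.151), and the apolipoprotein gene APOC1 at 9.61 ± 0.254 against 5.85 ± 0.333 (adjusted p = 0.169). The interferon-inducible gene EPSTI1 stood at 20.3 ± 1.94 against 10.7 ± 1.69 (adjusted p = 0.194). CALML5, a calmodulin-like gene, stood at 2.8 ± 0.745 against 0.297 ± 0.21 (adjusted p = 0.0847). ZNF165, MUSTN1, EFCC1 and CCDC113 were higher as well, with log2 differences from 0.56 for CCDC113 to 0.98 for ZNF165.

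Among the lower genes, SELE, the endothelial adhesion molecule E-selectin, stood at 0.154 ± 0.0474 RPKM in pacing and 2.25 ± 1.31 in sham (log2 difference -1.42, adjusted p = 0.244), and BIRC3, an inhibitor of apoptosis and NF-kB target, at 1.69 ± 0.165 against 4.78 ± 1.39 (-1.08, adjusted p = 0.21). The basement membrane collagen COL4A2 stood at 8.16 ± 0.382 against 14.3 ± 2.19 (-0.73, adjusted p = 0.242). Its neighbour and partner chain COL4A1, chosen after its value was seen, stood at 10.2 ± 0.521 against 20.7 ± 4.57 (-0.92, adjusted p = 0.251). DECR1, an enzyme of unsaturated fatty acid oxidation, stood at 18.7 ± 0.546 against 30.4 ± 1.63 (-0.67, adjusted p = 0.151). NEIL1, a DNA glycosylase of base excision repair, stood at 1.09 ± 0.243 against 2.93 ± 0.627 (-0.90, adjusted p = 0.222). ASPHD1 (-1.11) and ZG16B (-0.56) were lower without passing. MIR144 had 0 reads in pacing and 12 in sham, at least 3.45-fold lower when the floor is taken over the arm. Of the genes named in advance, BDNF stood at 4.45 ± 0.402 against 3.88 ± 1.6 RPKM (adjusted p = 0.788), the antioxidant regulator NFE2L2 at 12.3 ± 0.432 against 14.5 ± 5.66 (adjusted p = 0.849), its inhibitor KEAP1 at 19.6 ± 0.515 against 20.8 ± 3.42 (adjusted p = 0.884) and APP at 706 ± 74.6 against 723 ± 87.4 (adjusted p = 0.951). Each of these 4 differences was smaller than the spread between samples and changed sign when 1 library was left out.

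**Figure D1:**
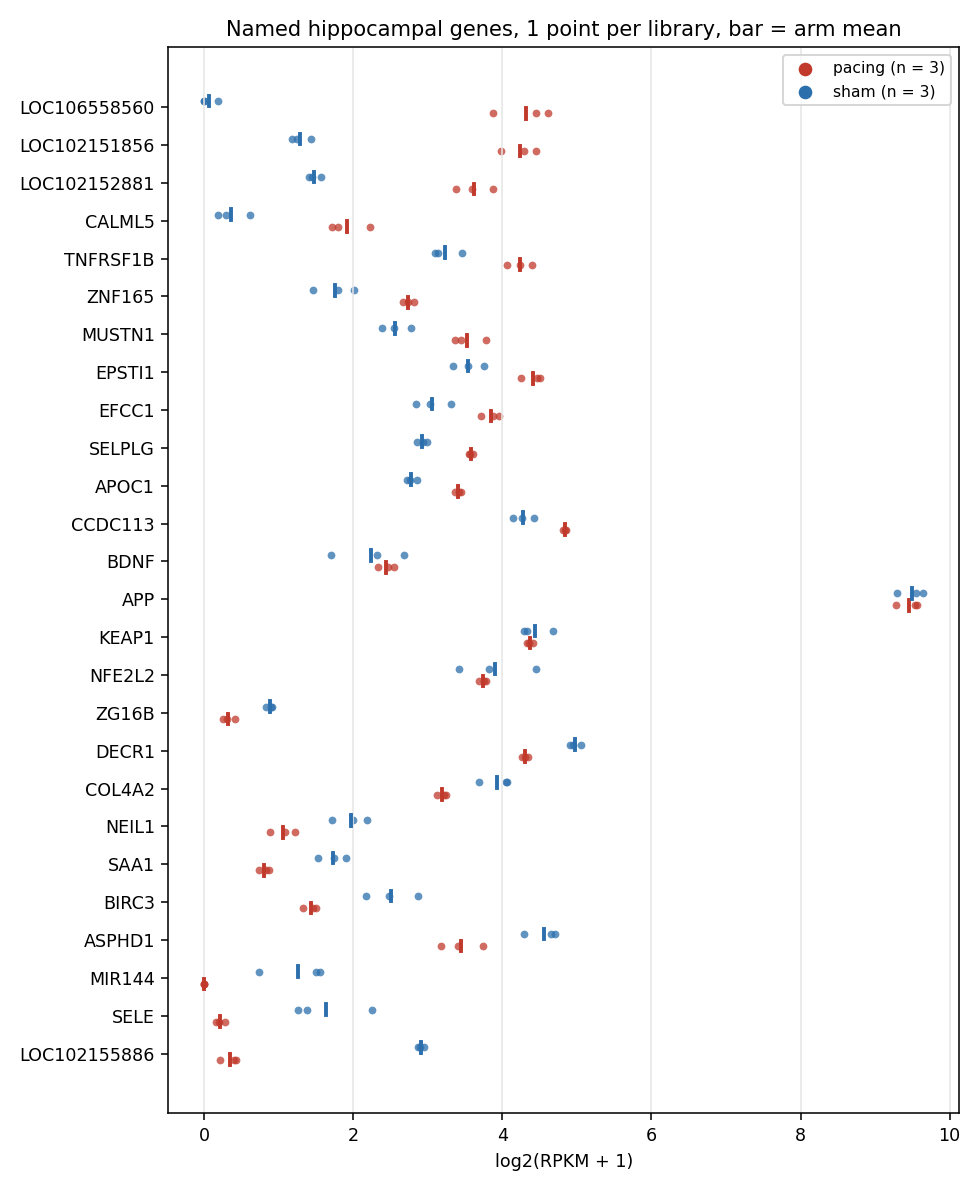
Hippocampal level of each named gene as log2(RPKM + 1) on the horizontal axis, with 1 point per library, pacing in red and sham in blue (n = 3 each) and a bar at each arm mean. LOC102155886 lies lowest in the order at a log2 difference of -2.56, and LOC106558560 is at the top at 4.25.

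Among the lists of genes fixed in advance, interferon-response genes, transcripts of the mitochondrial genome, microglial, oligodendrocyte precursor and pericyte markers and synaptic and excitatory neuron genes moved up in pacing, and ependymal, heat shock and immediate early genes moved down. Camera passed these 10 of 35 tested lists, 7 up and 3 down. By the mean of a list in each library, the arms were apart for the interferon, mitochondrial and pericyte lists alone. They overlapped for the other passing lists. For postsynaptic genes sham replicate 1 (0.18) lay above every pacing library (0.0091 to 0.12). For immediate early genes sham replicate 1 (-0.216) lay below pacing replicates 1 and 3 (-0.193 and -0.210). With an estimated correlation 0 of the 35 passed, and the smallest adjusted p = 0.707 with an estimated correlation. fry gave 2 lists with an unadjusted p under 0.05 and 0 after adjustment. Over all genes 0 members of any list passed, and 9 members passed when adjusted over the list alone. Other splits of the 6 libraries gave up to 17 passing lists against the 10 of the real split.

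All 16 tested interferon-response genes, which are induced in antiviral signalling, were higher in pacing (median log2 difference 0.34, adjusted p = 9.46e-10; adjusted p = 0.707 with an estimated correlation). IFI44 stood at 6.68 ± 1.11 RPKM in pacing and 4.16 ± 0.506 in sham, HERC5 at 0.952 ± 0.197 against 0.508 ± 0.0524 and IFI44L at 1.97 ± 0.6 against 1.03 ± 0.206, and 0 members passed adjusted over the list alone. All 16 were also higher under median-of-ratios and quantile scaling.

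Of 13 mitochondrially encoded genes 12 were higher in pacing by arm mean (median 0.67, adjusted p = 9.05e-09, or 0.707 with an estimated correlation). They included all 7 ND genes, subunits of respiratory complex I, which make up most of the list. For ND4, ND4L and COX3, sham replicate 1 (6060, 8210 and 11650 RPKM) lay above every pacing library. ND5 stood at 2441 ± 157 RPKM against 1092 ± 375, ND6 at 10436 ± 1053 against 5734 ± 1365, ND1 at 2190 ± 227 against 1186 ± 587, ND2 at 5286 ± 342 against 3385 ± 992 and ND3 at 1886 ± 111 against 953 ± 525. These 5 passed adjusted over the list alone (0.0144 for ND5, 0.0205 for ND6, 0.045 for each of the other 3) and 0 passed over all genes. ATP6, chosen after its value was seen and the most abundant after ATP8, stood at 34440 ± 3043 against 35951 ± 3152 RPKM, the member that was lower. Under median-of-ratios scaling all 13 were higher, and under quantile scaling, which holds the highest ranks in place, 9 were higher and 2 lower. Mitochondrial reads made up 8.75 ± 0.429% of reads in pacing and 7.26 ± 1.23% in sham. Neighbouring mitochondrial genes overlap and the strand setting is not stated, so reads in the overlaps cannot be assigned to either strand. For the same reason a feature may hold reads of the opposite strand over its whole length. This applies to ND6 on the minus strand and to ND5 beside it.

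**Figure D2:**
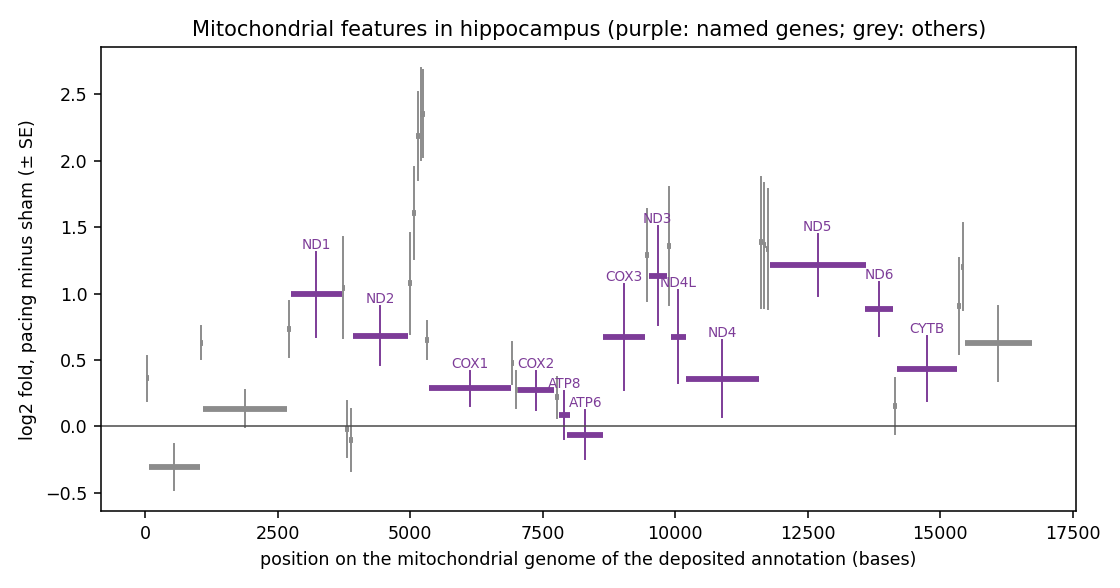
Log2 difference between pacing and sham (vertical axis, ± SE, n = 3 each) of each annotated mitochondrial feature along the mitochondrial genome in bases (horizontal axis), with named genes in purple and features without a symbol in grey. ND5 lies at 1.21 and ATP6 at -0.06, while unnamed features between ND2 and COX1 reach 2.35.

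Microglial markers moved up as a list, with 9 of 14 higher (median 0.19, adjusted p = 0.00704; adjusted p = 0.878 with an estimated correlation). The members differed in direction. CD74, the invariant chain of MHC class II, stood at 50.9 ± 4.78 RPKM against 34.2 ± 2.74 and the homeostatic marker TMEM119 at 1.61 ± 0.171 against 0.897 ± 0.201; both passed adjusted over the list alone (0.0159 and 0.0225). DLA-DRA, an MHC class II chain chosen after its value was seen, stood at 21.4 ± 2.13 against 12.1 ± 2.5 (adjusted p = 0.301). The microglial list did not pass without sham replicate 1 or without sham replicate 3 (adjusted p = 0.133 and adjusted p = 0.0592). Oligodendrocyte precursor markers were higher in 6 of 7 (median 0.20, adjusted p = 0.0135; adjusted p = 0.707 with an estimated correlation), with OLIG2 at 4.16 ± 0.293 against 2.78 ± 0.806. That list did not pass without pacing replicate 1, sham replicate 1 or sham replicate 3 (adjusted p = 0.0609, 0.114 and 0.0749). Pericyte and smooth muscle markers were higher in 9 of 11 (median 0.13, adjusted p = 0.0376; adjusted p = 0.707 with an estimated correlation), with the smooth muscle myosin MYH11 at 13.8 ± 0.435 against 11.8 ± 0.738 and RGS5 at 9.75 ± 0.356 against 8.25 ± 0.962. Their call was lost under median-of-ratios scaling (adjusted p = 0.0697) and without pacing replicate 1, pacing replicate 2 or sham replicate 3 (adjusted p = 0.0581, 0.0676 and 0.448).

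Postsynaptic density genes were higher in 17 of 20 (median 0.20, adjusted p = 0.00704; adjusted p = 0.878 with an estimated correlation) and excitatory neuron markers in 10 of 13 (median 0.27, adjusted p = 0.0315; adjusted p = 0.878 with an estimated correlation). The scaffold SHANK1 stood at 24.5 ± 0.412 against 21.1 ± 2.06 RPKM and its relative SHANK3 at 4.89 ± 0.709 against 4.01 ± 0.485. The kinase subunit CAMK2B went the other way by arm mean, at 6.81 ± 2.18 against 20.1 ± 14.6. Of the excitatory markers, the vesicular glutamate transporter SLC17A7 stood at 85.5 ± 12.5 against 68.9 ± 17.7, NEUROD2 at 32.3 ± 5.9 against 26.1 ± 7.14 and CAMK2A at 217 ± 32.4 against 179 ± 51. Sham replicate 2 had the lowest mean of both lists, -0.38 for postsynaptic and -0.40 for excitatory genes relative to the mean of all libraries. Without sham replicate 2 neither list passed (adjusted p = 0.922 and adjusted p = 0.511), and the mean of the postsynaptic list turned to -0.026. The excitatory list also failed under median-of-ratios scaling, under quantile scaling and without pacing replicate 2 or sham replicate 3 (adjusted p = 0.0751, 0.128, 0.134 and 0.0845).

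Ependymal markers, genes of ciliated cells lining the ventricles, were lower in 8 of 8 (median -0.48, adjusted p = 0.00427; adjusted p = 0.707 with an estimated correlation), with FOXJ1 at 0.29 ± 0.0889 against 0.783 ± 0.271 RPKM and HYDIN at 0.392 ± 0.148 against 0.982 ± 0.413. The list did not pass without sham replicate 1 or without sham replicate 3 (adjusted p = 0.0791 and adjusted p = 0.0629). Heat shock and unfolded protein genes were lower in 14 of 14 (median -0.24, adjusted p = 0.00905; adjusted p = 0.878 with an estimated correlation), 13 of 14 under median-of-ratios scaling, with HSPA8 at 499 ± 16.9 against 599 ± 21.5, DNAJB1 at 5.25 ± 0.451 against 9.7 ± 3.8 and HERPUD1 at 7.69 ± 0.82 against 10.8 ± 2.69. Immediate early genes, the transcripts induced fast by neuronal activity and by handling of tissue, were lower in 12 of 14 (median -0.46, adjusted p = 0.0317; adjusted p = 0.878 with an estimated correlation), with FOS at 0.421 ± 0.125 against 5.75 ± 6.37, FOSB at 1.9 ± 0.777 against 3.12 ± 0.523 and JUNB at 3.72 ± 0.752 against 7.12 ± 3.45. Sham replicate 2 had the highest mean of both lists, 0.40 and 0.69 above the mean of all libraries. Without sham replicate 2 neither passed (adjusted p = 0.108 for heat shock and adjusted p = 0.128 for immediate early genes). The immediate early list also failed at a pseudocount of 5 and without pacing replicate 2 or sham replicate 3 (adjusted p = 0.0623, 0.0501 and 0.0592).

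The other 25 tested lists did not pass. Of the cell type lists, the median log2 difference was 0.06 for dentate granule and CA neuron and 0.06 for endothelial markers (adjusted p = 0.145 for each), 0.14 for choroid plexus (0.463), 0.02 for leukocyte (0.431), 0.01 for meningeal fibroblast (0.489), 0.00 for oligodendrocyte (0.516), -0.10 for astrocyte (0.995) and -0.15 for reactive astrocyte genes (0.276). The median was 0.04 for presynaptic vesicle (adjusted p = 0.239), 0.01 for neurotrophin and plasticity (0.489) and -0.02 for Alzheimer-related genes (0.995). It was -0.13 for proinflammatory cytokine and NF-kB genes (adjusted p = 0.151), in which SELE passed adjusted over the list alone (0.00745), -0.13 for hypoxia and glycolysis (0.242), -0.10 for complement (0.489), -0.11 for glucocorticoid response (0.489), -0.09 for apoptosis (0.489) and -0.05 for autophagy and lysosome genes (0.995). It was 0.02 for NRF2 targets (adjusted p = 0.399), 0.02 for oxidative stress enzymes (0.472) and 0.02 for nuclear oxidative phosphorylation genes (0.472). In 5 lists the median was negative while camera's direction was up: circadian clock (-0.02, adjusted p = 0.672), inhibitory neuron (-0.08, 0.786), ribosomal protein (-0.03, 0.818), tight junction (-0.06, 0.821) and extracellular vesicle uptake (-0.00, 0.988). The passing count was 6 without sham replicate 3.

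**Figure D3:**
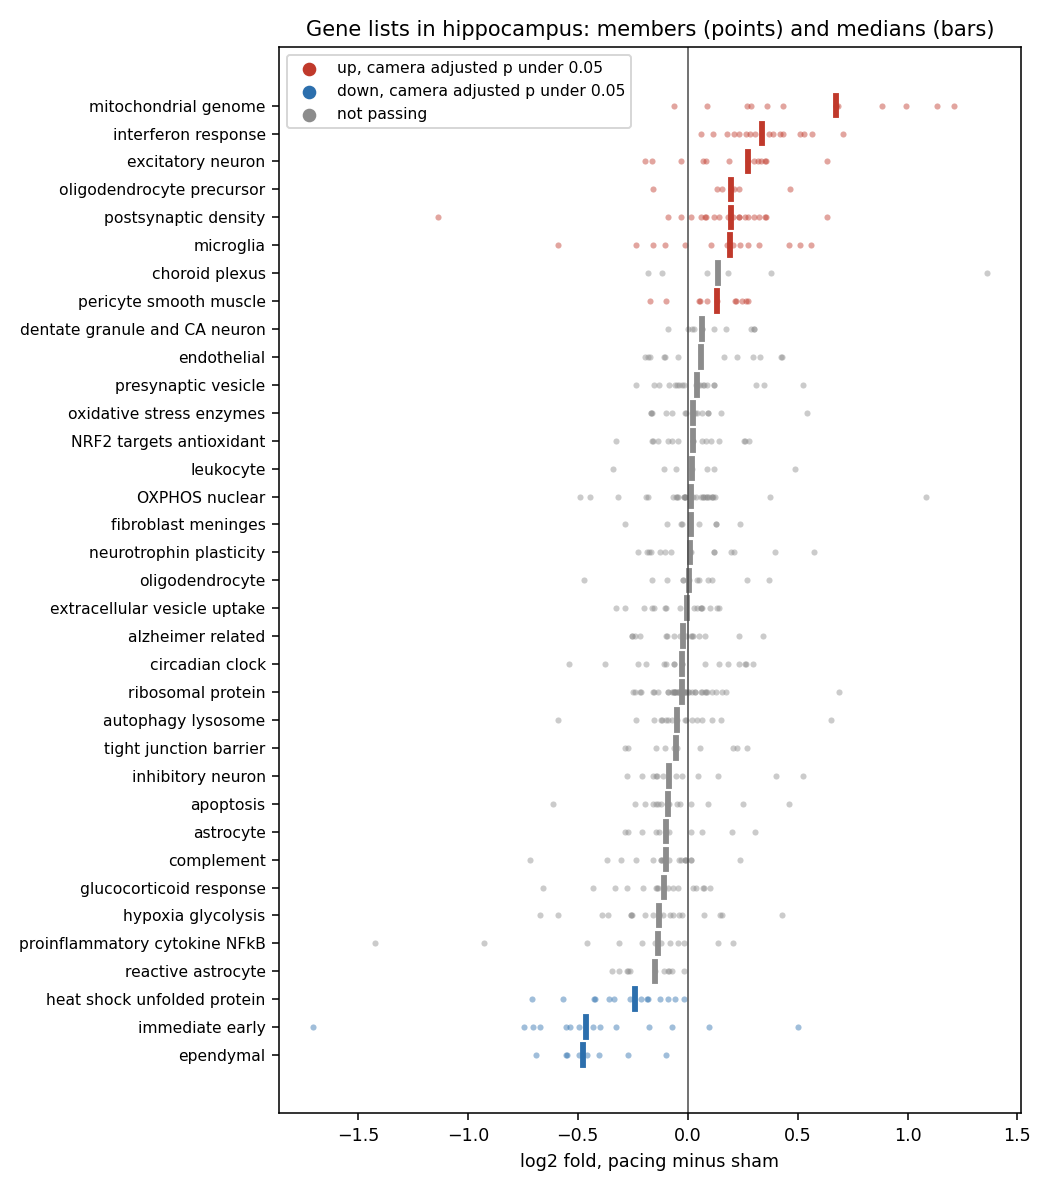
Log2 difference between pacing and sham (horizontal axis) of the tested members of each gene list, as points, with the list median as a bar (n = 3 libraries per arm); red lists passed camera upwards, blue lists downwards and grey lists did not pass. Medians run from -0.48 for ependymal markers to 0.67 for the mitochondrial genome.

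The exosome comparison asked which miRNAs in vesicles of epicardial fat differed with pacing. No named miRNA passed, and 3 numbered entries listed in all libraries of 1 arm and at 0 in the other did. novel_30 rose from 0 reads to 922 in pacing, at least 395-fold, with 20616 ± 18562 RPM (SD, n = 3; adjusted p = 2.56e-04). novel_2 rose from 0 reads to 180, at least 77.1-fold (adjusted p = 0.0261), and novel_109 fell from 1148 reads in sham, 26245 ± 31145 RPM, to 0 in pacing, at least 298-fold lower (adjusted p = 2.56e-04). The floors were taken over the arm. How numbered entries were called is not given, so a 0 may mean that an entry was not called in a library. The fold bounds hold only if a 0 means no reads. The sequences and genomic origin of these entries are not given in the sources used here.

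Among named miRNAs, cfa-miR-21, a miRNA abundant in fibrotic and inflamed tissue, stood at 22142 ± 9540 RPM in pacing and 9976 ± 5378 in sham (log2 difference 1.20 ± 0.51 SE, adjusted p = 0.616). cfa-miR-140 stood at 209 ± 116 against 734 ± 170 RPM (-1.98 ± 0.87 SE, adjusted p = 0.616). These were the 2 named miRNAs of 171 tested with an unadjusted p under 0.05. The muscle miRNA cfa-miR-1 had 4 reads in pacing and 26 in sham. cfa-miR-133a and cfa-miR-133c, with the same values in every library, had 3 against 15 reads (3.89-fold, 1.10 to 20.98). The other named miRNAs picked by rank were cfa-miR-92a at 1679 ± 259 against 889 ± 173 RPM, cfa-miR-10a at 2401 ± 1982 against 998 ± 536, cfa-miR-181a at 471 ± 266 against 185 ± 321, cfa-miR-381 at 712 ± 276 against 286 ± 263, cfa-miR-223 at 748 ± 512 against 522 ± 789 and cfa-miR-455 at 256 ± 114 against 78.7 ± 78.3. cfa-miR-193a had 2 against 10 reads (3.89-fold, 0.83 to 36.5), while cfa-miR-374b had 4 against 0, cfa-miR-135a-5p 0 against 4 and cfa-miR-138a 0 against 5, which this depth cannot separate. Of the other most abundant miRNAs, cfa-miR-125b stood at 47156 ± 18800 against 78965 ± 30433 RPM (log2 difference -0.73, adjusted p = 0.616), cfa-miR-199 at 85746 ± 19100 against 95056 ± 31716 and cfa-let-7a at 77185 ± 13571 against 87754 ± 38193. cfa-miR-26a, cfa-miR-16, cfa-let-7b and cfa-let-7f had log2 differences of 0.12, 0.23, -0.10 and 0.08, smaller than the spread between samples.

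Of 314 tested entries 2 rose and 1 fell in limma, and 19 had an unadjusted p under 0.05 (10 higher, 9 lower). edgeR on recovered reads tested 73 entries and passed 0, as did named miRNAs scaled to their own reads. The count of passing entries was 6 without pacing replicate 1, 5 without sham replicate 2 and 7 without sham replicate 3. Arms did not overlap for 13 entries, and the other splits of the 6 libraries gave 5 to 33. Libraries correlated at r of 0.389 to 0.568 within arms and 0.333 to 0.434 between arms over all entries. Over named miRNAs alone r was 0.703 to 0.773 within and 0.700 to 0.811 between arms. The median entry differed by 0.10 on the log2 scale, and by -0.21 under quantile scaling, which turned the sign of cfa-miR-199, cfa-let-7a, cfa-miR-26a, cfa-miR-16 and cfa-let-7f.

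Camera passed 0 of 14 lists, with 0 at an unadjusted p under 0.05 in fry and 0 passing with an estimated correlation; 1 list, muscle and heart miRNAs, had an unadjusted camera p under 0.05. Its 7 tested members included cfa-miR-133a and cfa-miR-133c, which had the same values in every library, so the list counted these values under both names. The members had a median log2 difference of -2.11 (adjusted p = 0.671), with 3 higher and 4 lower. That median was the value of cfa-miR-206, at 0 RPM in pacing and 26.5 ± 45.9 in sham. Inflammation miRNAs had a median of 1.99 (adjusted p = 0.686) and leukocyte miRNAs 1.75 (0.707), with 6 of 7 and 8 of 10 higher. In both lists sham replicate 1 had the lowest mean, -2.57 and -2.47. The inflammation median was the value of cfa-miR-31, at 20.7 ± 35.8 RPM in pacing and 0 in sham. At this depth the log2 values of rare miRNAs turn on very few reads, so these list medians do not measure a fold change in level. The median was 0.64 for the imprinted Dlk1-Dio3 cluster, 0.48 for regulators of NFE2L2 and KEAP1 from the literature, -0.11 for brain-enriched, -0.63 for miR-17-92, 0.50 for hypoxia, 0.11 for platelet and endothelial and 0.23 for erythrocyte miRNAs, each with an adjusted p = 0.799. It was 0.24 for liver, kidney and gut miRNAs (adjusted p = 0.86). Median and mean differed in sign for adipose (0.07 and -0.26, adjusted p = 0.799), fibrosis (-0.15 and 0.25, adjusted p = 0.897) and let-7 miRNAs (-0.09 and 0.30, adjusted p = 0.929). Without pacing replicate 2, 1 list passed.

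**Figure D4:**
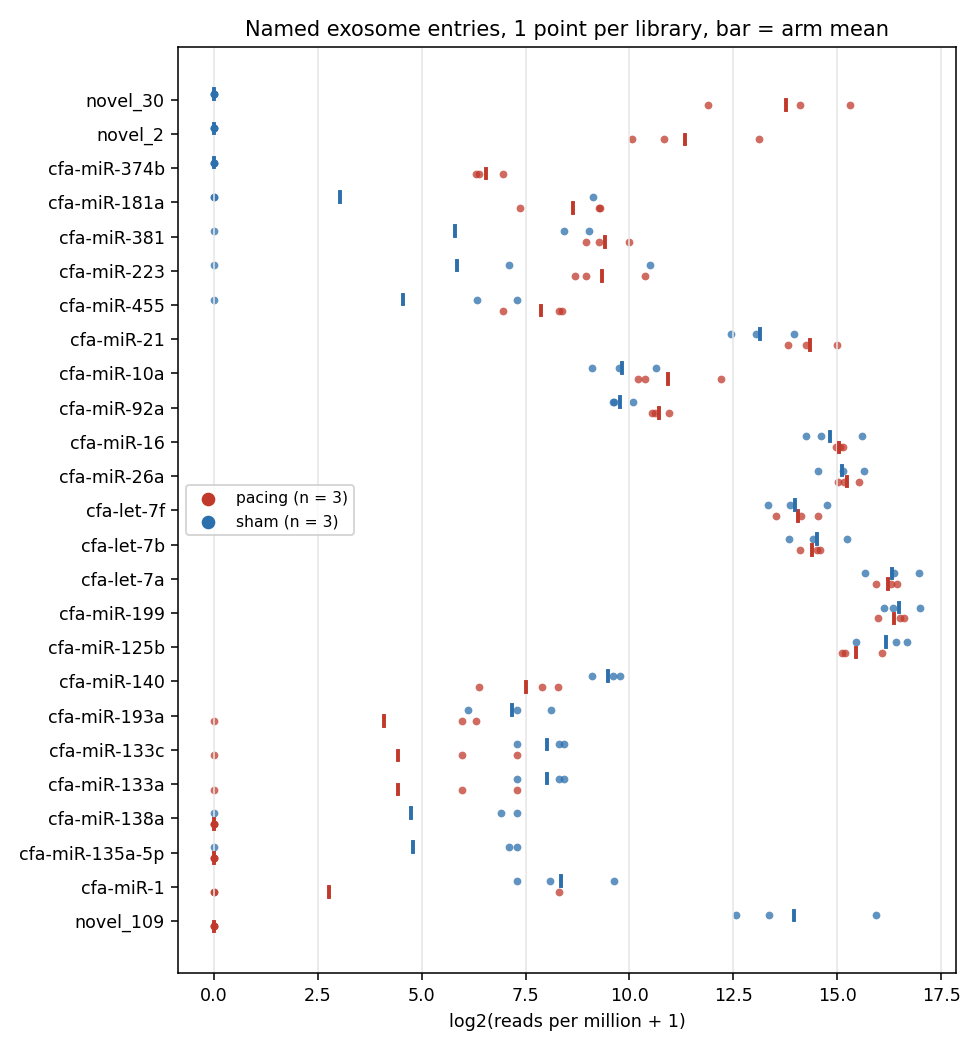
Level of each named exosome entry as log2(RPM + 1) on the horizontal axis, with 1 point per library, pacing in red and sham in blue (n = 3 each) and a bar at each arm mean. novel_30 and novel_2 lie at 0 in every sham library and novel_109 at 0 in every pacing library.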

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

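Quantile scaling of the lists and exosome values scaled to named miRNA reads were chosen after the data were seen. In hippocampus LOC102151856 and LOC106558560 passed in 16 of 16 alternatives, LOC102155886 in 15 of 15 (the higher filter removed it) and LOC102152881 in 15 of 16 (adjusted p = 0.0524 without pacing replicate 2). The number of passing genes was 7 with no filter, 23 with library weights and 75 at an unadjusted p under 0.05 and a fold of at least 2, and ran from 3 (without pacing replicate 2) to 95 (without sham replicate 1) when 1 library was left out. Passing exosome entries numbered 0 in edgeR on recovered reads, which tested 73 entries, 0 scaled to named miRNA reads, which left numbered entries out, and 19 at the unadjusted threshold, and 2 to 7 without 1 library. novel_109 passed in 14 of 15 alternatives, novel_30 in 12 and novel_2 in 8. Gene lists numbered 0 with an estimated correlation and 6 (without sham replicate 3) to 12 (without sham replicate 2) without 1 library; miRNA lists numbered 0 to 1. Each of the 10 passing lists kept camera's direction in 13 alternatives, although the mean of the postsynaptic list turned to -0.026 without sham replicate 2, and the interferon and mitochondrial lists passed in 12 of them. Same-numbered deviations from the arm mean correlated at -0.11, 0.06 and -0.01 in hippocampus and at -0.0026, 0.00038 and 0.049 in exosomes. Only exosome replicate 3 correlated best with its own number. With 3 libraries per arm this check cannot exclude pairing by replicate number. With the replicate block 7 genes, 2 exosome entries, 10 gene lists and 0 miRNA lists passed. Single values that turned sign belonged to differences under their spread. APP was 0.031 with median-of-ratios scaling, 0.018 in edgeR and -0.13 to 0.058 without 1 library. ATP6 was 0.0021 with median-of-ratios scaling and 0.00032 with library weights. Without 1 library BDNF ran from -0.057 to 0.44, NFE2L2 from -0.40 to 0.11 and KEAP1 from -0.14 to 0.058. Quantile scaling gave 0.24 for cfa-miR-199, 0.10 for cfa-let-7a, -0.20 for cfa-miR-26a, -0.041 for cfa-miR-16 and -0.21 for cfa-let-7f. Without 1 library cfa-miR-199 ran from -0.31 to 0.13, cfa-let-7a from -0.44 to 0.21, cfa-miR-26a from -0.16 to 0.38, cfa-miR-16 from -0.052 to 0.62, cfa-let-7b from -0.43 to 0.27 and cfa-let-7f from -0.25 to 0.47. Where the construction of a setting does not give the cause of a moved count, the cause was not tested.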

Other observations

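Beyond the genes described above, single members of lists that did not pass, and 2 genes outside the lists, stood apart in every library (n = 3 per arm), none of them past the threshold over all genes. All were chosen after their values were seen. Full separation of the arms held for 2605 of 16090 tested genes (16.2%), so it does not single these genes out. The glucose transporter SLC2A3 stood at 20.4 ± 1.25 RPKM in pacing and 33.7 ± 8.47 in sham (log2 difference -0.67, adjusted p = 0.378). In the apoptosis list PMAIP1, a proapoptotic gene, stood at 13.6 ± 2.3 against 9.57 ± 0.585 (0.46, adjusted p = 0.396). The activity-regulated synaptic gene NPTX2 stood at 9.42 ± 1.1 against 6.03 ± 1.24 (0.58, adjusted p = 0.378). In the clock list ARNTL stood at 3.55 ± 0.322 against 4.89 ± 0.266 (-0.37, adjusted p = 0.391) and CRY2 at 13.2 ± 0.42 against 11.1 ± 1.06 (0.23, adjusted p = 0.544). Of the Alzheimer-related genes, the beta-secretase BACE1 stood at 44.9 ± 1.74 against 53.8 ± 4.64 (-0.25, adjusted p = 0.516) and APOE at 2576 ± 357 against 2021 ± 185 (0.34, adjusted p = 0.546). Outside the lists, SYCE1, a synaptonemal complex gene on chromosome 28, and LOC102154876 next to it stood at 0.237 ± 0.328 and 0.126 ± 0.112 RPKM in pacing against 4.93 ± 2.78 and 2.38 ± 1.08 in sham (adjusted p = 0.272 and adjusted p = 0.201).

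Of the patterns weighed here, all tests except the counts over other splits of the libraries were chosen after the result was seen.

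Unnamed gene models separated the arms in hippocampus, as LOC102155886 and 3 other passing models did. Counting noise at low read number is argued against by the lowest bound of the 4 counting intervals of the ratio, 5.34, far above 1. The 4 models were picked as passing in the same reads, so the intervals are not an independent check. Reads moving from LOC102155886 to another annotated gene within 80 kb are argued against, since the 6 such genes changed by -5.59 RPM where it lost 4.45 RPM. That check could not see copies elsewhere or reads left uncounted, and it did not cover the 3 other models. Differences between dogs unrelated to the arm remain open: 25 genes were fully separated with a mean ratio of at least 4 in the real split and 8 in the highest of the other 9 splits, and 25 exceeds 3 times 8, or 24, by less than its counting spread of 5. A candidate explanation that involves the arm, a response of serum amyloid A and linked genes to pacing, was not tested apart from these counts, and inherited differences between few dogs could give the same separation.

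The 7 ND transcripts of the mitochondrial genome were higher in pacing (mean log2 difference 0.85 ± 0.34 SE, n = 3 each). Mitochondrial DNA in the libraries would raise every feature by a like amount, but the control region rose by 81.0 ± 42.8 RPKM (SE) against a mean of 1842 ± 709 for the 7 genes, a ratio of 0.044 (at most 0.393 at 2 SE), which argues against DNA as the whole cause. A larger mitochondrial share of all RNA would raise every mitochondrial gene by a like ratio. The mean log2 level of the 7 genes less that of the 6 other genes differed by 0.57 ± 0.19 SE between arms without overlap. The difference did not pass the bound of 0.5 by 2 SE, and the grouping into ND and other genes was chosen after the values were seen. This test therefore could not decide, and a larger share stays open as the whole cause or as part of it. A single aberrant sham library stays open as well, since the mean log2 difference fell to 0.59 ± 0.38 SE without sham replicate 3. A change in the processing or stability of these transcripts may be a candidate explanation, but it was not tested, and unnamed features between ND2 and COX1 differed by more (2.35 ± 0.34 SE from 5179 to 5215, adjusted p = 0.175).

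Numbered exosome entries separated the arms, in that novel_30, novel_2 and novel_109 were in all libraries of 1 arm alone. Counting noise at low depth is argued against by the fewest reads of the 3 entries, 180 against a floor of 3, if a 0 means no reads. Those 180 reads, of novel_2, were 13, 23 and 144 in pacing replicates 1, 2 and 3. Entries scattered over libraries without regard to the arm stay open and are consistent with the counts: of 14 numbered entries seen in exactly 3 libraries, 3 (21.4%) fell in all of 1 arm where chance gives 10% (exact one-sided binomial p = 0.158). Numbered entries were in 1 library alone in 88 of 143 cases, with a median of 35.5 reads there, whereas 28 of 178 named miRNAs were, with a median of 1 read. Of the 88, 82 had over 10 reads there, against 0 of the 28. The 3 entries may therefore be no more than such scatter, and no biological explanation of them was tested. Whether a 0 of a numbered entry stands for no reads or for no call was not tested either.

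The 10 splits of the 6 libraries are too few for a share under 0.05. Genes changed in hippocampus numbered 4 in the real split and 0 in the highest other, so that 1 split gave as many. Gene lists numbered 10 in the real split and 17 in the highest other, and 6 splits gave as many. Exosome entries numbered 3 against 2 in the highest other (1 split), and miRNA lists 0 against 1 (10 splits).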
